A study of Zea mays subsp. mays with 9 samples.

How the data were processed

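Total RNA of 9 arrays was labelled in one colour (Cy3) and hybridised to custom Agilent arrays, with RNA integrity numbers above 8 and 200 ng of input RNA per the labels. The deposited scanner files came from Agilent Feature Extraction 11, per the submitters' processing notes, and version 11.5.1.1, per the file headers. Per the file headers, the processed signal is an intensity on a linear scale, background subtracted and detrended within each array and not normalised between arrays, and the median spot and background signals are intensities before any correction. Detection, outlier and saturation flags of 0 or 1 were used as deposited. The authors also deposited a value table. Set against the scanner values, it holds log2 median spot signals after quantile normalisation by the authors (correlation 0.999 or higher with each array, column medians 6.77 to 6.78, quantiles of the columns within 0.0222); no source used here states that scale, and the table was used as an alternative.

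Control spots and outlier-flagged spots (4 to 85 of 176026 per array) were left out, no spot was saturated, and spots of one probe were averaged. Values were log2 of the processed signal minus the 75th percentile of each array, taken over the 50047 probes well above background on all 9 arrays because under 50% of probes were detected. Probes were kept if well above background on all 3 arrays of at least 1 line (60811 probes), and a gene was the mean of its kept probes, which gave 45386 genes, 36394 with 1 probe. Of called genes with several probes, 76 of 2304, 57 of 1353 and 39 of 1390 had probes past the test in opposite directions for cytTC316 against TC208, cytW633 against TC208 and cytW633 against cytTC316. Replicate spots had a coefficient of variation of 10.9 to 13.6%.

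Gene names came from NCBI RefSeq's table for the assembly Zm-B73-REFERENCE-NAM-5.0, used only for names and for which genes neighbour each other, since the gene models on the array are older and their build is not given in the sources used here. Of 107027 gene models, 18295 matched 1 RefSeq gene, 522 matched several and 2521 had a name, 1940 of them among the genes tested. Several gene models could match the same RefSeq gene and were counted apart. Models that share a name, as for Nrt1.1 and NAC1, may thus be 1 gene. No gene model matched an organelle gene, so transcripts of the chloroplast and mitochondrial genomes are not analysed here.

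All 9 arrays were fitted in one model with a mean per line (limma 3.58.1 in R 4.3.3, lmFit and eBayes; files were read with data.table, version 1.17.8), and the 3 comparisons between lines were tested with Benjamini-Hochberg adjustment at 0.05. Where a gene was not well above background on any array of a line, its fold was written as at least a value. The dim line was set at the lowest well-above-background signal of each array or at the gene's own signal, whichever was higher. This is not a strict lower bound, since signals near background are uncertain. Named genes were chosen by a rule fixed before the data were examined: the 12 highest and 12 lowest log2 fold changes among named genes past the test whose lines did not overlap, and up to 3 changed members per list, those of largest change. A list with no changed member gave the one with the smallest adjusted p. For both cytolines the rule took up to 10 genes per direction, ranked by the smaller of their changes, and it took at most 2 genes without a name per direction. The text prints a part of that set, and the examples of a list are among its largest changes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

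Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. There were 27 lists fixed before the data were examined, as symbols and words of gene descriptions. The names table has symbols and no descriptions, so 15 of them had a tested gene and 5 had at least 5 (C4 cycle, pentatricopeptide repeat proteins, jasmonate and oxylipin, anthocyanin and flavonoid, cell wall). A further 19 lists by symbol were written after the table's symbols were seen and before any comparison was computed. Overlap of the cytolines was set beside independent lists and beside 20 simulations of unchanged groups that share the TC208 arrays. Runs of neighbouring genes were tested against 1000 shuffles of the gene order.

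The arrays lay on 6 slides with 1 scan each. Slides 1 and 2 held TC208 and cytW633, slide 3 held TC208 and cytTC316, and slides 4 to 6 held 1 array each, so the slide was tested as a fixed and as a random block and within slides 1 to 3, there on genes called without the slide's arrays. With the slide as a fixed block, the arrays of slides 4 to 6 do not enter the comparisons. cytTC316 is then represented by its array on slide 3 alone, and the spread comes only from slides 1 and 2. That fit is thus no test of the 3 arrays per line. All TC208 arrays lay at position 4 of their slide, all cytTC316 arrays at position 3 and those of cytW633 at positions 2 and 3. Alternatives were other normalisations (quantile, median, normexp with an offset of 50, the authors' values), other filters on dim probes, other rules for several probes, the replicate number as a block, the 2 compared lines alone, trend and robust moderation, array weights, stricter thresholds, and leaving out each array. Mean spot signals were not used here, so normexp was run on median spot signals. The model was tested on simulated data of the 45386 genes with 200 changed genes per comparison, 50 of each size. It recovered 4% of 1.5-fold, 60% of 2-fold and 98% of 4-fold changes for cytTC316 against TC208. These shares were 6%, 46% and 92% for cytW633 against TC208, and 8%, 52% and 96% between the cytolines. Far more genes were called in the real data. Because the adjusted p depends on the share of genes that change, these recoveries do not carry over to the real comparisons.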

Results

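The study measured seedling transcripts of maize cytolines, which are lines that carry the nucleus of one inbred line in the cytoplasm of another. TC208 was the nucleus donor, with its own cytoplasm. cytTC316 and cytW633 were its cytolines, with the cytoplasm of TC316 and of W633, so both were compared with TC208 to ask which nuclear transcripts differed when the cytoplasm was replaced. Each line had 3 arrays from seedlings of 9 days, called biological replicates in the series' design text. Each array was a one-colour Agilent gene expression array with 133671 probes for 107027 gene models, of which 42.4 to 47.7% were well above background on an array. The number of arrays limits the precision of every value. Across the 45386 genes tested, arrays of one line correlated at 0.979 to 0.988. TC208 and cytTC316 correlated at 0.891 to 0.897, TC208 and cytW633 at 0.920 to 0.934, and the cytolines with each other at 0.923 to 0.937.

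**Figure D1:**
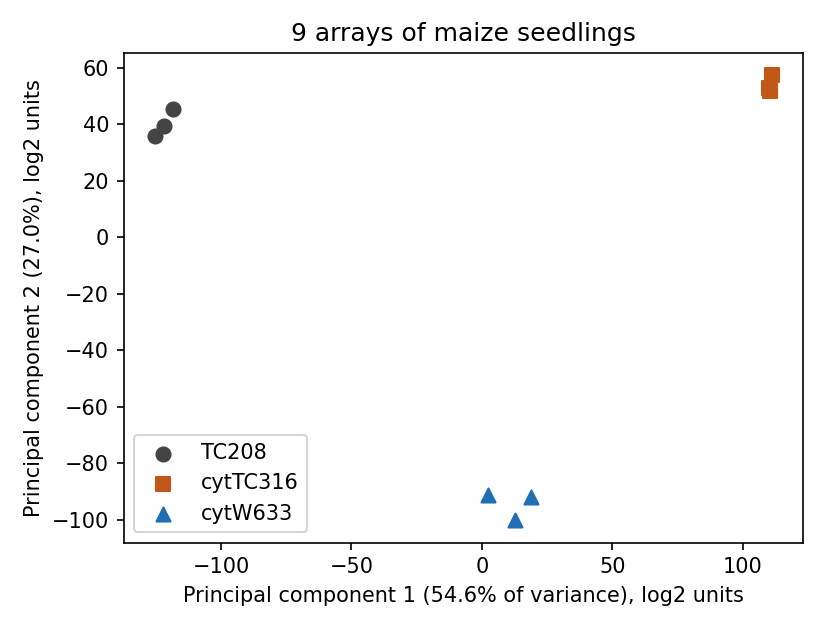
First and second principal components (54.6% and 27.0% of the variance, in normalised log2 units) of the 9 arrays, with 1 point per array and 3 arrays per line. The arrays of each line lie together, TC208 and cytTC316 at opposite ends of the first component and cytW633 apart on the second.

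In cytTC316, his2b5 (GRMZM2G342515), which encodes a histone H2B, was at least 691-fold higher than in TC208 (log2 fold change 9.43 ± 0.31 SE, adjusted p 4.0e-08). Its normalised log2 signal was 2.07 ± 0.33 in cytTC316 (SD, n = 3) and -7.36 ± 0.54 in TC208, where it was not well above background on any array. TIFY4 (GRMZM2G445634), of the family that includes the repressors of jasmonate signalling, was at least 436-fold higher (log2 fold change 8.77 ± 0.19 SE, adjusted p 4.2e-09), and lox6 (GRMZM2G040095), a lipoxygenase, rose 43.7-fold (log2 fold change 5.45 ± 0.11 SE, adjusted p 2.6e-09). At the other end, LIP (GRMZM2G102183) was at least 70.9-fold lower (log2 fold change -6.15 ± 0.48 SE, adjusted p 1.2e-05) and the terpene synthase gene tps26 (GRMZM2G030583) fell 24.6-fold (log2 fold change -4.62 ± 0.23 SE, adjusted p 6.2e-07). In all, 6963 genes were higher and 5216 lower in cytTC316 at an adjusted p under 0.05 in limma, 26.8% of those tested, and 3782 and 2586 of them by at least 2-fold. The split was more even, 6166 higher and 6004 lower, on the authors' values, and 6249 higher and 5940 lower after normexp.

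Other named genes with large increases were ADPRT-1 (GRMZM5G831712, at least 184-fold), a poly(ADP-ribose) polymerase, the nitrate transporter genes Nrt1.1 (GRMZM2G141491, at least 116-fold) and Nrt1.1 (GRMZM2G041631, at least 80.9-fold), and FHA17 (GRMZM2G424241, at least 88.6-fold). They included eks1 (GRMZM2G049538, at least 53.8-fold), an ent-kaurene synthase of gibberellin synthesis, dhs2 (GRMZM2G703077, at least 38.6-fold), ATSWI3B (GRMZM2G064328, at least 25.1-fold), a subunit of SWI/SNF chromatin remodelling, and the calcium sensor CBL2-1 (GRMZM2G069500, at least 21.8-fold). Large decreases were those of glucA (GRMZM2G125032, at least 63.1-fold), the peroxidase PER2 (GRMZM2G040638, at least 30.01-fold), the transcription factor genes NAC1 (GRMZM2G018553, at least 23.8-fold) and NAC1 (GRMZM2G336533, 23.6-fold), and CNR5 (GRMZM5G892035, at least 21.6-fold). Also lower were EREB85 (GRMZM2G124524, at least 15.2-fold), an AP2/EREBP factor, spds2 (GRMZM2G047867, 14.3-fold), a spermidine synthase, and PRR59 (GRMZM2G135446, at least 13.9-fold), a pseudo-response regulator of the clock. Of NAC1 (GRMZM2G336533), 2 of the 3 cytTC316 arrays gave a signal well above background. A fold written as at least a value belongs to a gene that was not well above background on any array of one line. The dim line was set at its own signal or, where that was lower, at the lowest well-above-background signal of its arrays. That signal, -7.80 to -7.68 on the TC208 arrays, is no detection limit. In TC208 his2b5 lay above it at -7.36 and was still not well above background. For his2b5 and others the value is thus the measured ratio to a signal near background, and the true fold may be smaller. The genes his2b5, TIFY4, CBL2-1, ATSWI3B, dhs2, glucA, PER2 and both Nrt1.1 genes were each measured by 1 probe. Among genes without a name, GRMZM2G165201 (at least 2248-fold) and GRMZM2G121293 (at least 1244-fold) were the most increased, and GRMZM2G177242 (1951-fold) and GRMZM2G012276 (1641-fold) among the most decreased, each with 1 of the 3 cytTC316 arrays well above background. Their folds depended on single arrays: the log2 fold change of GRMZM2G177242 was -12.24 without cytTC316 replicate 2 and -10.17 without replicate 3, against -10.93 with all arrays, and that of GRMZM2G012276 was -11.63 without replicate 2, against -10.68.

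Genes of the chloroplast and mitochondrion moved both ways in cytTC316. Of all genes tested, 26.8% were called in this comparison. Lists were matched by symbol, and of the 1940 genes tested that had a name, 567 were called. The list counts for cytTC316 are to be read beside these shares, and a list near them does not stand out. Of the photosynthesis list, 3 of 26 members rose, 4 fell and 19 did not pass (3 up and 5 down adjusted over the list alone). lhcb4 (GRMZM2G103101), the antenna protein CP29, rose 10.8-fold (log2 fold change 3.43 ± 0.18 SE, adjusted p 8.0e-07), and the antenna gene Cab-m7 (GRMZM2G402936, 3.00-fold) and the ferredoxin gene fdx3 (GRMZM2G053458, 7.67-fold) were lower, the latter on 1 of its 2 probes (log2 fold change 0.0751, adjusted p 0.755 on its brighter probe). In the C4 cycle list, 0 of 23 members rose, 4 fell and 19 did not pass (0 up and 4 down adjusted over the list alone). Decreases were those of mdh6 (GRMZM2G129513, 1.70-fold), the NADP malate dehydrogenase of the mesophyll chloroplast, and CYPPDKZM2 (GRMZM2G097457, 1.87-fold) on 1 of its 2 probes (log2 fold change -0.30, adjusted p 0.133 on its brighter probe). In the list of plastid gene expression and assembly, 10 of 52 members rose, 6 fell and 36 did not pass (12 up and 6 down adjusted over the list alone). Increases were those of toc34 (GRMZM2G159777, at least 4.95-fold), an import receptor, CFM2 (GRMZM2G347322, 3.34-fold), a splicing factor of chloroplast introns, and, on 1 of its 2 probes, Emb12 (GRMZM2G119691, 6.80-fold), whose other probe did not pass (log2 fold change -0.0162, adjusted p 0.960 on its brighter probe). In tetrapyrrole and carotenoid synthesis, 2 of 22 members rose, 6 fell and 14 did not pass (2 up and 6 down adjusted over the list alone). DVR (GRMZM2G063048, 1.66-fold), a reductase of chlorophyll synthesis, was higher and lls1 (GRMZM2G339563, 1.47-fold), an oxygenase of chlorophyll breakdown, lower, and HO-1 (GRMZM2G101004, 2.37-fold) was lower on 1 of its 2 probes (log2 fold change 0.22, adjusted p 0.395 on its brighter probe). In mitochondrial energy metabolism, 6 of 41 members rose, 5 fell and 30 did not pass (6 up and 5 down adjusted over the list alone). rf2 (GRMZM2G058675, 2.46-fold), an aldehyde dehydrogenase and fertility restorer, was higher, and mTRF22 (GRMZM2G161146, 6.65-fold), of the mTERF family, and the small heat shock gene hsp22 (GRMZM2G007729, 2.31-fold) were lower.

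Of the stress and defence lists, all but the benzoxazinoid genes had both members that rose and members that fell. Among heat shock genes and chaperones 3 of 32 members rose, 9 fell and 20 did not pass (3 up and 10 down adjusted over the list alone). The heat shock factors Hsf26 (GRMZM2G003489, 8.92-fold) and Hsf03 (GRMZM2G164909, 8.52-fold) were lower and hsbp1 (GRMZM2G085924, 4.88-fold), which binds such factors, was higher. For antioxidants 2 of 31 members rose, 5 fell and 24 did not pass (2 up and 5 down adjusted over the list alone). PER2 was lower. MSRA5.1 (GRMZM2G376918) was 7.11-fold lower as the mean of its probes, which passed in opposite directions (higher, log2 fold change 0.69, adjusted p 0.00855 on its brighter probe). For glutathione transferases 5 of 21 members rose, 3 fell and 13 did not pass (5 up and 3 down adjusted over the list alone). gst42 (GRMZM2G025190, 3.96-fold) and gst30 (GRMZM2G044383, 4.36-fold) were higher, the latter 2.79-fold without TC208 replicate 3. Of jasmonate and defence genes 8 of 58 members rose, 10 fell and 40 did not pass (8 up and 10 down adjusted over the list alone), with TIFY4, lox6 and eks1 the most increased. The list takes in eks1 by its symbol, although that gene is of gibberellin synthesis. Of the benzoxazinoid genes 3 of 10 members rose, 0 fell and 7 did not pass (3 up and 0 down adjusted over the list alone). glu1 (GRMZM2G016890, 8.47-fold), a beta-glucosidase that acts on benzoxazinoid glucosides, bx1 (GRMZM2G085381, 4.11-fold), the indole-forming first enzyme, and bx2 (GRMZM2G085661, 3.28-fold) rose. Of abscisic acid and dehydration genes 8 of 46 members rose, 3 fell and 35 did not pass (7 up and 3 down adjusted over the list alone). The receptor PYL7 (GRMZM2G144224, 2.25-fold) and the phosphatase PP2C8 (GRMZM2G019819, 6.29-fold) (1 of the 3 TC208 arrays well above background) were higher and dbf1 (GRMZM2G061487, 2.64-fold) was lower. Without TC208 replicate 3 bx1 was 6.22-fold and PP2C8 10.3-fold higher.

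In the anthocyanin and phenylpropanoid list 7 of 35 members rose, 3 fell and 25 did not pass (8 up and 5 down adjusted over the list alone). Laccase-17 (GRMZM2G305526, 12.4-fold) (2 of the 3 cytTC316 arrays well above background; 8.19-fold without cytTC316 replicate 1) and f3h (GRMZM2G062396, 6.02-fold), flavanone 3-hydroxylase, were lower. The shorter anthocyanin list fixed before the data were examined had 6 of 11 members higher and 0 lower (6 up and 0 down adjusted over the list alone): a2 (GRMZM2G345717, 3.39-fold), the anthocyanidin synthase, bronze (GRMZM2G165390, 2.29-fold), a flavonoid glucosyltransferase, and A1 (GRMZM2G026930, 2.17-fold), dihydroflavonol reductase, rose. For cell wall genes 7 of 50 members rose, 8 fell and 35 did not pass (8 up and 11 down adjusted over the list alone). The expansin gene expB7 (GRMZM2G342246, 10.2-fold) was higher. For cytosolic ribosomal proteins 4 of 28 members rose, 4 fell and 20 did not pass (5 up and 4 down adjusted over the list alone). rps10 (GRMZM2G095511, 3.55-fold) was higher and rps4 (GRMZM2G125271, 5.64-fold) was lower. Of nitrogen and sugar metabolism 6 of 26 members rose, 1 fell and 19 did not pass (6 up and 1 down adjusted over the list alone), both Nrt1.1 genes among the increases. Among lists kept for differences in harvest hour, growth stage or tissue, clock, photoperiod and phytochrome genes gave 5 higher and 4 lower of 21 (5 up and 4 down adjusted over the list alone), with ZCN4 (GRMZM2G075081, 7.75-fold) higher, which like the other ZCN genes of the list is of the FT/TFL1-like family of flowering regulators and not a clock gene, and PRR59 lower. Histones and cell cycle genes gave 6 and 2 of 41 (5 up and 2 down adjusted over the list alone), seed storage 2 and 1 of 9 (2 up and 1 down adjusted over the list alone), and root markers 4 and 3 of 29 (4 up and 3 down adjusted over the list alone), with the phosphate transporter gene pht3 (GRMZM2G045473, 4.07-fold) lower.

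No list as a whole shifted in cytTC316 in limma's camera test (lowest adjusted p 0.127 among the lists by symbol and 0.103 among the earlier ones). Signs differed between list median, mean and test for these lists, with median and mean in parentheses: tetrapyrrole and carotenoid genes (0.05 and -0.02), antioxidants (0.02 and -0.25), glutathione transferases (0.03 and 0.18), abscisic acid and dehydration genes (-0.06 and 0.05), anthocyanin and phenylpropanoid genes (0.01 and -0.04), cell wall genes (-0.22 and 0.04), cytosolic ribosomal proteins (0.02 and -0.04) and root markers (0.06 and -0.04), where the test pointed down. In 19326 genes (42.6%) the 3 values of one line all lay above those of the other, against 10% by chance. Slide 3 held an array of each line. Of 10201 genes called from the other 7 arrays, 91.1% had the same direction within slide 3, against 58.7% of genes not called, in a test chosen after the data were seen. With the slide as a fixed block, which leaves 1 residual degree of freedom, 4225 genes were called, 3877 of them shared with the fit without it, and 55 of the 84 calls of named genes held. For cytTC316 that fit rested on the pair of arrays on slide 3, with the spread taken from slides 1 and 2. When each array was left out in turn, 76 of the 84 calls held every time.

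In cytW633, the named genes with the largest increases were again his2b5, at least 652-fold higher than in TC208 (log2 fold change 9.35 ± 0.31 SE, adjusted p 6.4e-08), and TIFY4, at least 388-fold higher (log2 fold change 8.60 ± 0.19 SE, adjusted p 6.3e-09). The homeobox gene HB115 (GRMZM2G021339) was at least 139-fold lower (log2 fold change -7.12 ± 0.12 SE, adjusted p 2.4e-09). BX5 (GRMZM2G063756), a cytochrome P450 of benzoxazinoid synthesis, fell 55.1-fold (log2 fold change -5.78 ± 0.19 SE, adjusted p 6.8e-08), from a normalised log2 signal of 0.31 ± 0.24 in TC208 to -5.48 ± 0.26 in cytW633 (SD, n = 3), with 2 of the 3 cytW633 arrays well above background. In all, 4141 genes were higher and 3043 lower at an adjusted p under 0.05 in limma (15.8% of those tested), 2437 and 1460 of them by at least 2-fold. Which direction held more genes depended on the scaling, with 3474 higher and 3682 lower on the authors' values, 3540 higher and 3658 lower after normexp and 3573 higher and 3704 lower with the percentile over all probes.

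Further increases among named genes were those of Nrt1.1 (GRMZM2G141491, at least 131-fold), Nrt1.1 (GRMZM2G041631, at least 101-fold), FHA17 (at least 117-fold), ADPRT-1 (at least 55.1-fold), eks1 (at least 50.5-fold), lox6 (29.8-fold), ATSWI3B (at least 29.5-fold) and dhs2 (at least 21.4-fold). They were followed by the haemoglobin gene Hb2 (GRMZM2G168898, 16.7-fold) and lw1 (GRMZM2G027059, 16.6-fold), the last enzyme of the plastid isoprenoid pathway. Decreases were those of LIP (at least 61.04-fold), NAC1 (GRMZM2G336533, 19.4-fold), f3h (17.02-fold), and NAC1 (GRMZM2G018553, 16.2-fold). Smaller ones were those of mTRF22 (7.94-fold), GF14-6 (GRMZM2G102499, 7.48-fold), a 14-3-3 protein (log2 fold change -0.45, adjusted p 0.0653 on its brightest probe), opr7 (GRMZM2G148281, 7.36-fold), a reductase of jasmonate synthesis, afd1 (GRMZM2G059037, 4.72-fold), a meiotic cohesin, and Hsf03 (4.09-fold). For the NAC1 genes 2 and 1 of the 3 cytW633 arrays were well above background. Among genes without a name, GRMZM2G165201 (at least 2325-fold) and GRMZM2G102811 (at least 624-fold) were most increased and GRMZM2G177242 (at least 4890.1-fold) and GRMZM2G097297 (at least 2593-fold) most decreased.

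The list of plastid gene expression and assembly was lower as a whole in cytW633: 1 of 52 members rose, 10 fell and 41 did not pass (1 up and 11 down adjusted over the list alone), with a median log2 fold change of -0.17 and a camera adjusted p of 0.0104, against an adjusted p = 0.855 with an estimated correlation. Its decreases included GRMZM2G472651 (10.5-fold), which encodes a subunit of thylakoid Tat transport, prpl35-1 (GRMZM2G136559, 1.94-fold), a plastid ribosomal protein gene that lost its call in 5 of 9 fits with 1 array left out, and PPR8522 (GRMZM5G884466, 1.88-fold) on 2 of its 3 probes (log2 fold change -0.33, adjusted p 0.575 on its brightest probe). In the same comparison more root markers were higher than lower, 6 of 29 against 1 (median 0.14, camera p 0.0452 and adjusted p 0.164). The plastid list's call was also lost with the slide as a fixed block (adjusted p 0.468), after quantile normalisation (0.120), without TC208 replicate 3 (0.213) and without cytW633 replicate 1 (0.0587). Its adjusted p ranged from 0.00229 to 0.855 over the alternatives. Within slide 1 the plastid list's median was -0.05, and within slide 2 it was -0.12.

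No other list passed the camera test in cytW633. The counts below are to be read beside the 15.8% of all genes tested that were called in this comparison, and the 321 called of the 1940 with a name. In the photosynthesis list 2 of 26 members rose, 2 fell and 22 did not pass (2 up and 5 down adjusted over the list alone). lhcb4 (8.21-fold) was higher on 1 of its 2 probes (log2 fold change 0.36, adjusted p 0.256 on its brighter probe), and Cab-m7 (4.02-fold) was lower. In the C4 cycle 1 of 23 members rose, 2 fell and 20 did not pass (0 up and 1 down adjusted over the list alone). CYPPDKZM2 (1.80-fold) was lower. In mitochondrial energy metabolism 2 of 41 members rose, 2 fell and 37 did not pass (2 up and 2 down adjusted over the list alone). rf2 (1.63-fold) was higher. In tetrapyrrole and carotenoid synthesis 2 of 22 members rose, 4 fell and 16 did not pass (2 up and 6 down adjusted over the list alone). dxs2 (GRMZM2G493395, 8.09-fold), the first enzyme of the plastid isoprenoid pathway, was higher, and vp14 (GRMZM2G014392, 2.34-fold), the cleavage enzyme of abscisic acid synthesis, was lower. For heat shock genes and chaperones 2 of 32 members rose, 5 fell and 25 did not pass (3 up and 5 down adjusted over the list alone). Hsf26 (3.08-fold) was lower and HSF6 (GRMZM2G059851, at least 3.56-fold) was higher. For antioxidants 3 of 31 members rose, 4 fell and 24 did not pass (3 up and 6 down adjusted over the list alone). PER42 (GRMZM2G126261, 10.4-fold) (on 2 of its 3 probes) and the thioredoxin gene trxh1 (GRMZM2G424053, 3.05-fold) were higher. For glutathione transferases 4 of 21 members rose, 2 fell and 15 did not pass (4 up and 3 down adjusted over the list alone). gst30 (5.99-fold) and gst24 (GRMZM2G032856, 3.63-fold) were higher, the former 3.83-fold without TC208 replicate 3. Among jasmonate and defence genes 3 of 58 members rose, 4 fell and 51 did not pass (3 up and 4 down adjusted over the list alone), TIFY4 and lox6 among the increases. Of the benzoxazinoid genes 1 of 10 members rose, 3 fell and 6 did not pass (1 up and 4 down adjusted over the list alone). BX5 and the glucosyltransferase bx8 (GRMZM2G085054, 1.68-fold) were lower. For abscisic acid and dehydration genes 9 of 46 members rose, 1 fell and 36 did not pass (9 up and 1 down adjusted over the list alone). PYL7 (2.36-fold) was higher.

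In the anthocyanin and phenylpropanoid list 4 of 35 members rose, 2 fell and 29 did not pass (5 up and 3 down adjusted over the list alone). Of cell wall genes 3 of 50 members rose, 3 fell and 44 did not pass (3 up and 3 down adjusted over the list alone). The cellulose synthase gene CesA-8 (GRMZM2G177631, 3.93-fold) was lower. Of cytosolic ribosomal proteins 3 of 28 members rose, 2 fell and 23 did not pass (3 up and 2 down adjusted over the list alone). rps10 (5.85-fold) was higher. Of nitrogen and sugar metabolism 3 of 26 members rose, 0 fell and 23 did not pass (3 up and 0 down adjusted over the list alone). The earlier anthocyanin list had 0 members higher and 0 lower of 11. Clock, photoperiod and phytochrome genes gave 3 higher and 3 lower of 21 (3 up and 3 down adjusted over the list alone), with the flowering regulator ZCN4 (7.17-fold) higher. The counts were 2 and 1 of 41 for histones and cell cycle (1 up and 0 down adjusted over the list alone). Root markers gave 6 and 1 of 29 (7 up and 1 down adjusted over the list alone), with the potassium transporter genes HAK9 (GRMZM2G166738, 3.17-fold) (on 2 of its 4 probes) and HAK7 (GRMZM2G020766, 1.95-fold) higher. None of 9 seed storage genes passed, bap2 (GRMZM2G152655) having the smallest adjusted p (log2 fold change 0.45 ± 0.13 SE, adjusted p 0.0501). Signs differed between list median, mean and test for these lists, with median and mean in parentheses: mitochondrial energy metabolism (0.03 and -0.00858), tetrapyrrole and carotenoid genes (-0.09 and 0.13), anthocyanin and phenylpropanoid genes (0.06 and -0.04), cell wall genes (0.05 and 0.07), cytosolic ribosomal proteins (-0.14 and 0.01), earlier jasmonate and oxylipin genes (0.02 and 0.54) and earlier cell wall genes (0.11 and 0.02), where the test pointed down, and glutathione transferases (-0.00816 and 0.23), where it pointed up.

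In 14323 genes (31.6%) the values of cytW633 and TC208 did not overlap, against 10% by chance. Slides 1 and 2 held both lines. Of 4692 and 5715 genes called without the arrays of slide 1 and of slide 2, 97.04% and 92.6% had the same direction within the slide left out in the same test, against 64.4% and 59.4% of genes not called. With the slide as a fixed block 3500 genes were called, 3310 of them shared, and 47 of the 71 calls of named genes held; 56 held in every fit with 1 array left out.

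Most genes that changed in both cytolines changed the same way. Among the named genes with the largest shared increases, his2b5, TIFY4, both Nrt1.1 genes, FHA17, eks1 and ATSWI3B did not differ between the cytolines (adjusted p 0.252 or higher), while ADPRT-1 was 3.34-fold and lox6 1.46-fold lower in cytW633 than in cytTC316 (adjusted p 0.00123 and 0.00802). Among the shared decreases were LIP, both NAC1 genes, mTRF22, GF14-6, afd1 and lox10 (GRMZM2G015419), a lipoxygenase lower by 3.66-fold in cytTC316 and 3.77-fold in cytW633, on 4 and 3 of its 5 probes. The brightest probes of lox10 (adjusted p 0.183 and 0.352) and GF14-6 (0.255 and 0.0653) did not pass in cytTC316 and cytW633. f3h was 2.82-fold lower in cytW633 than in cytTC316, and Hsf03 2.08-fold higher (adjusted p 0.00187 and 0.00773). In total 2967 genes were higher and 1888 lower in both cytolines, 1736 and 931 of them by at least 2-fold in both, and 117 changed in opposite directions.

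**Figure D2:**
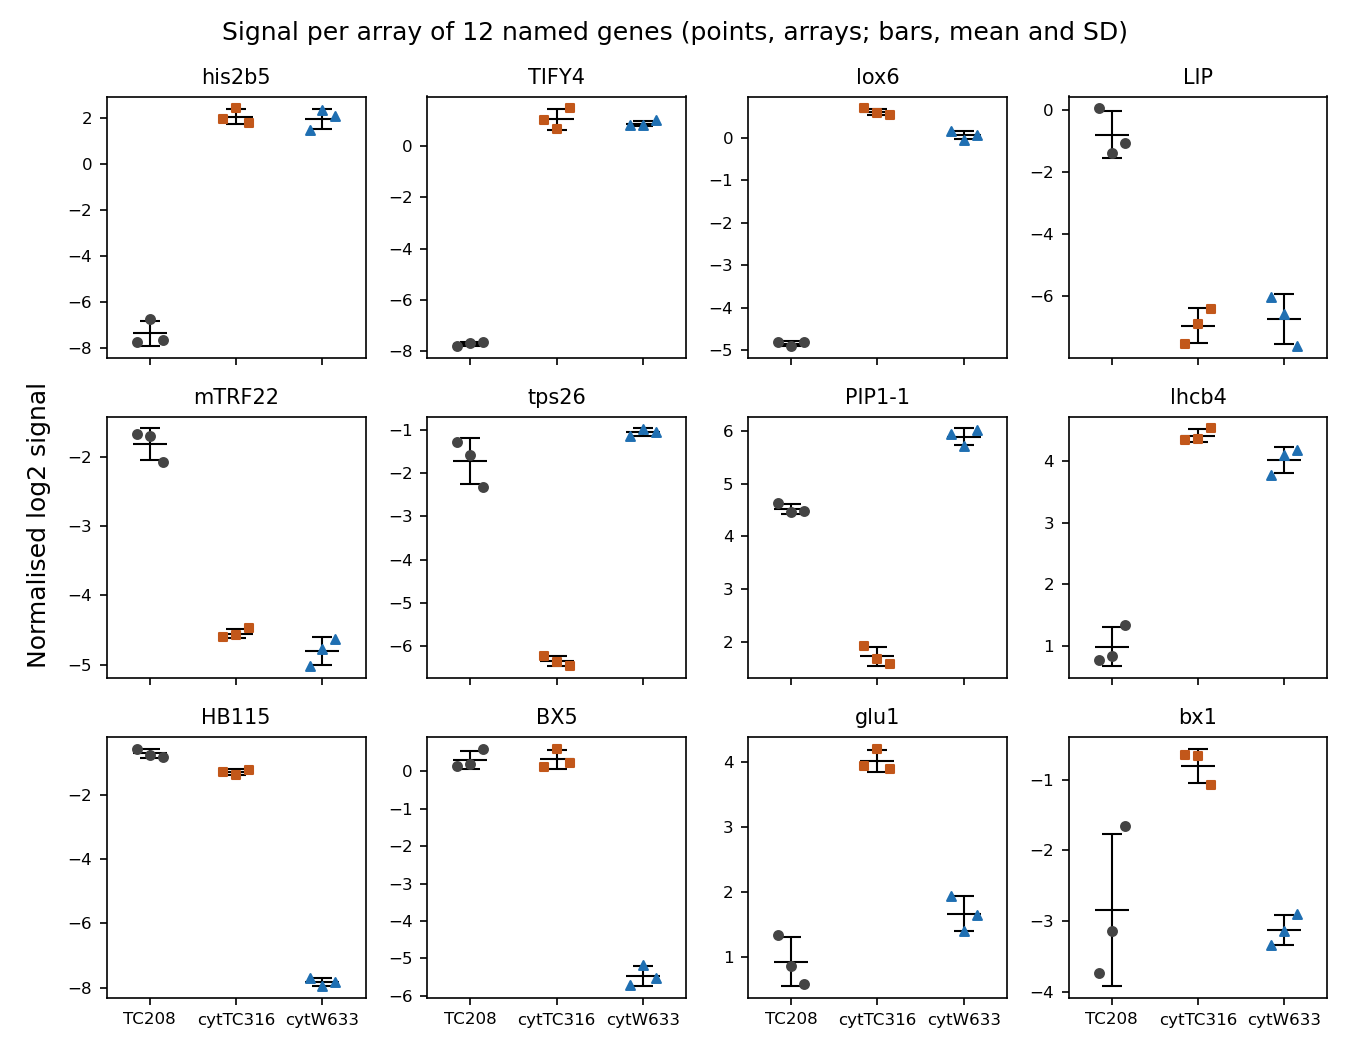
Normalised log2 signal (y axis, log2 signal minus the 75th percentile of its array) of 12 named genes in TC208, cytTC316 and cytW633. Points are the 3 arrays of a line and bars the mean and SD; his2b5, TIFY4 and lox6 are high in both cytolines, LIP and mTRF22 low in both, PIP1-1 lies on opposite sides of TC208, and HB115 and BX5 are low in cytW633.

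Both comparisons shared the TC208 arrays. Independent lists of these sizes would share 635 higher and 349.7 lower genes, and unchanged groups simulated against the same controls shared 0 in each of 20 simulations, a value for no effect that does not show how much the controls add where genes do change. The fold changes of the cytolines correlated at 0.658 across genes, which are not independent replicates, against 0.501 simulated; their covariance was 0.635 against 0.0270 simulated, a difference of 0.608. With the TC208 arrays split 1 and 2 between the cytolines in 6 ways, so that neither comparison used an array of the other, the covariance was 0.572 to 0.615; between arrays of the same slide (slide 3 for cytTC316, 1 and 2 for cytW633) it was 0.602. This split was chosen after the data were seen. With 3 TC208 arrays, genes could not be called again with at least 2 separate controls for each cytoline, so part of the excess in shared calls may come from the common controls. Among the shared genes, 672 of the higher (22.6%) and 429 of the lower (22.7%) also differed between the cytolines. With the slide as a fixed block 1852 genes were called in both in the same direction.

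**Figure D3:**
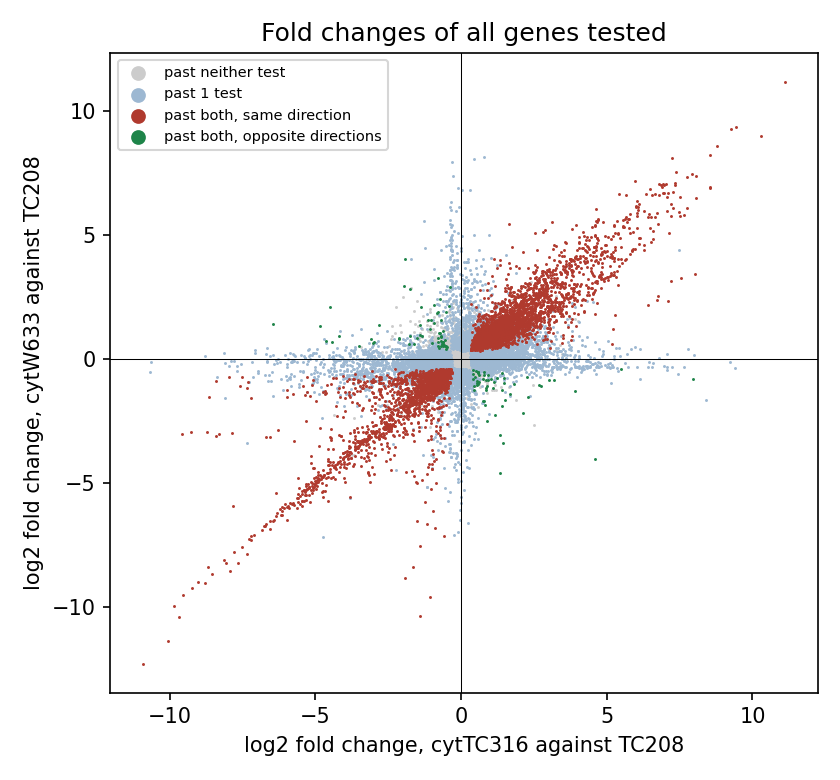
Log2 fold change against TC208 of each of the 45386 genes tested, cytTC316 on the x axis and cytW633 on the y axis, with 1 point per gene coloured by the tests it passed. Of the genes past both tests, 4855 lie in the quadrants of equal direction and 117 in the others.

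Between the cytolines, which by design carry the TC208 nucleus in different cytoplasms, tps26 was 39.2-fold higher in cytW633 than in cytTC316 (log2 fold change 5.29 ± 0.23 SE, adjusted p 4.1e-07) and the aquaporin gene PIP1-1 (GRMZM2G174807) 18.01-fold higher (log2 fold change 4.17 ± 0.14 SE, adjusted p 6.6e-08). HB115 was at least 92.7-fold lower (log2 fold change -6.53 ± 0.12 SE, adjusted p 2.9e-09) and BX5 55.5-fold lower (log2 fold change -5.79 ± 0.19 SE, adjusted p 8.0e-08), with 2 of the 3 cytW633 arrays well above background for it. In limma's camera test benzoxazinoid genes, the plastid list and the earlier anthocyanin list were lower in cytW633 as groups (adjusted p 7.6e-04, 2.1e-04 and 3.1e-04). With an estimated correlation none of these calls held (adjusted p = 0.590, 0.597 and 0.400), and with the slide as a fixed block the plastid list's did not (adjusted p 0.734). In all, 3342 genes were higher and 3904 lower in cytW633 (15.97% of those tested, adjusted p under 0.05 in limma), 1868 and 1922 of them by at least 2-fold. The direction with more genes turned with the slide as a fixed block (696 higher and 483 lower) and at an adjusted p under 0.01 (2023 higher and 1979 lower).

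Other named genes that were higher in cytW633 were glucA (at least 27.1-fold), PER2 (at least 18.9-fold), PRR59 (at least 16.2-fold), CNR5 (at least 14.4-fold), lw1 (14.1-fold), TIFY9 (GRMZM2G145412, at least 12.99-fold), EREB85 (at least 11.8-fold) and DOF10 (GRMZM2G435475, at least 11.6-fold). Lower were expB7 (12.7-fold), TAZ3 (GRMZM2G121115, 9.26-fold), GRMZM2G472651 (7.95-fold), the aquaporin gene TIP2-2 (GRMZM2G056908, 7.92-fold), and mbd111 (GRMZM2G025095, 7.90-fold), of the methyl-CpG-binding family. So were opr7 (6.66-fold), CNR7 (GRMZM2G119755, 6.06-fold), the annexin gene Ann7 (GRMZM2G064993, 5.77-fold) and AD1 (GRMZM2G167438, 5.62-fold). Emb12 was 8.18-fold lower on 1 of its 2 probes (log2 fold change -0.19, adjusted p 0.554 on its brighter probe). Among genes without a name, GRMZM2G465163 (1452-fold) was the most increased, and GRMZM2G590476 (at least 1059.8-fold) and GRMZM2G078324 (at least 851-fold) the most decreased.

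Of the benzoxazinoid genes 0 of 10 members rose, 7 fell and 3 did not pass (0 up and 7 down adjusted over the list alone), with a median log2 fold change of -0.81 and a camera adjusted p of 7.6e-04, against an adjusted p = 0.590 with an estimated correlation (range 2.3e-04 to 0.590 over the alternatives). Beside BX5, glu1 (5.09-fold) and bx1 (5.001-fold) fell. Whether the members of this list lie in a run of neighbouring genes was not tested, so their decreases may not be independent. The list's median against TC208 was -0.32 and 0.02 for cytW633 within slides 1 and 2, and 0.15 for cytTC316 within slide 3. Of the list of plastid gene expression and assembly, 1 of 52 members rose, 15 fell and 36 did not pass (1 up and 20 down adjusted over the list alone), toc34 among the decreases (at least 2.74-fold lower), with a median of -0.26 and a camera adjusted p of 2.1e-04. For this list the adjusted p = 0.597 with an estimated correlation and 0.734 with the slide as a fixed block (range 5.0e-05 to 0.734 over the alternatives), and its median for cytTC316 against TC208 within slide 3 was -0.05. Beside these decreases 8 of 29 root markers were higher and 1 lower in cytW633 (camera p 0.0124 and adjusted p 0.0588). Of the earlier anthocyanin and flavonoid list, 0 of 11 members rose, 6 fell and 5 did not pass (0 up and 6 down adjusted over the list alone), with decreases of a2 (4.49-fold), A1 (3.00-fold) and CHI (GRMZM2G155329, 2.00-fold), chalcone isomerase, and a camera adjusted p of 3.1e-04, against an adjusted p = 0.400 with an estimated correlation (range 1.9e-05 to 0.400 over the alternatives).

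Abscisic acid and dehydration genes were slightly higher in cytW633 (median 0.16, camera adjusted p 0.0371, adjusted p = 0.597 with an estimated correlation): 4 of 46 members rose, 2 fell and 40 did not pass (3 up and 2 down adjusted over the list alone), with dbf1 (3.32-fold) higher and DBP4 (GRMZM2G380377, 1.85-fold) lower. This call was lost with the slide as a fixed block (0.629) and without cytTC316 replicate 2 (0.0984), cytW633 replicate 1 (0.0535) or cytW633 replicate 3 (0.0940), with adjusted p from 0.0104 to 0.629 over the alternatives. The list's median against TC208 was -0.01 and 0.14 for cytW633 within slides 1 and 2, and 0.02 for cytTC316 within slide 3.

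No other list passed between the cytolines. Here 15.97% of all genes tested were called, and 369 of the 1940 with a name, to be set beside the counts below. In the photosynthesis list 0 of 26 members rose, 3 fell and 23 did not pass (1 up and 4 down adjusted over the list alone). In the C4 cycle 3 of 23 members rose, 0 fell and 20 did not pass (5 up and 1 down adjusted over the list alone). pck2 (GRMZM5G870932, 2.20-fold), a carboxykinase that releases carbon dioxide, and mdh6 (1.47-fold) were higher. Of mitochondrial energy metabolism 3 of 41 members rose, 3 fell and 35 did not pass (3 up and 2 down adjusted over the list alone). aldh5 (GRMZM2G097706, 2.18-fold) was higher. In tetrapyrrole and carotenoid synthesis 4 of 22 members rose, 3 fell and 15 did not pass (4 up and 6 down adjusted over the list alone). dxs2 (4.93-fold) was higher and vp14 (2.06-fold) was lower. Of heat shock genes and chaperones 7 of 32 members rose, 2 fell and 23 did not pass (7 up and 2 down adjusted over the list alone). Hsf26 (2.90-fold) and the disulfide isomerase gene pdi11 (GRMZM2G176443, 2.65-fold) were higher and hsbp1 (2.95-fold) was lower. For antioxidants 6 of 31 members rose, 5 fell and 20 did not pass (7 up and 5 down adjusted over the list alone). PER42 (10.3-fold) was higher on 2 of its 3 probes. For glutathione transferases 3 of 21 members rose, 2 fell and 16 did not pass (3 up and 2 down adjusted over the list alone). gst7 (GRMZM2G028556, 1.86-fold) was higher and GST26 (GRMZM2G363540, 1.85-fold) was lower. For jasmonate and defence 12 of 58 members rose, 6 fell and 40 did not pass (13 up and 6 down adjusted over the list alone), with tps26, TIFY9 and geb1 (GRMZM2G065585, 11.4-fold) among those higher. In the anthocyanin and phenylpropanoid list 7 of 35 members rose, 7 fell and 21 did not pass (7 up and 7 down adjusted over the list alone). lac3 (GRMZM2G169033, at least 9.57-fold) and Laccase-17 (8.57-fold) were higher (the latter well above background on 2 of the 3 cytTC316 arrays). Without cytTC316 replicate 1 geb1 was 7.58-fold and Laccase-17 5.66-fold higher. Of cell wall genes 7 of 50 members rose, 6 fell and 37 did not pass (11 up and 7 down adjusted over the list alone). CesA-8 (2.23-fold) was lower. Of cytosolic ribosomal proteins 4 of 28 members rose, 2 fell and 22 did not pass (6 up and 2 down adjusted over the list alone). rps4 (3.08-fold) was higher. Of nitrogen and sugar metabolism 2 of 26 members rose, 3 fell and 21 did not pass (3 up and 5 down adjusted over the list alone). NAR (GRMZM5G878558, 2.26-fold) and ivr2 (GRMZM2G089836, 1.57-fold) were lower.

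Root markers were higher in cytW633 more often than lower: 8 of 29 members rose, 1 fell and 20 did not pass (10 up and 2 down adjusted over the list alone), including pht3 (3.91-fold) and, on 2 of its 4 probes, HAK9 (3.58-fold), and as a list they did not pass (adjusted p 0.0588). Clock, photoperiod and phytochrome genes gave 2 higher and 3 lower of 21 (2 up and 3 down adjusted over the list alone), with ZCN16 (GRMZM2G127121, at least 4.80-fold), of the FT/TFL1-like family, lower and PRR59 (at least 16.2-fold) higher. Histones and cell cycle genes gave 1 and 1 of 41 (1 up and 1 down adjusted over the list alone) and seed storage 1 and 1 of 9 (1 up and 1 down adjusted over the list alone). Signs differed between list median, mean and test for these lists, with median and mean in parentheses: tetrapyrrole and carotenoid genes (-0.07 and 0.15), clock, photoperiod and phytochrome genes (-0.11 and 0.05), cytosolic ribosomal proteins (-0.10 and 0.05) and nitrogen and sugar metabolism (0.03 and 0.05), where the test pointed down, and antioxidants (-0.11 and 0.24) and glutathione transferases (-0.02 and 0.05), where it pointed up. In 15541 genes (34.2%) the values of the cytolines did not overlap, against 10% by chance. No slide held both cytolines; with the slide as a fixed block, through slides shared with TC208, 1179 genes were called, 1051 of them shared, and 27 of the 79 calls of named genes held, while 60 held in every fit with 1 array left out.

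**Figure D4:**
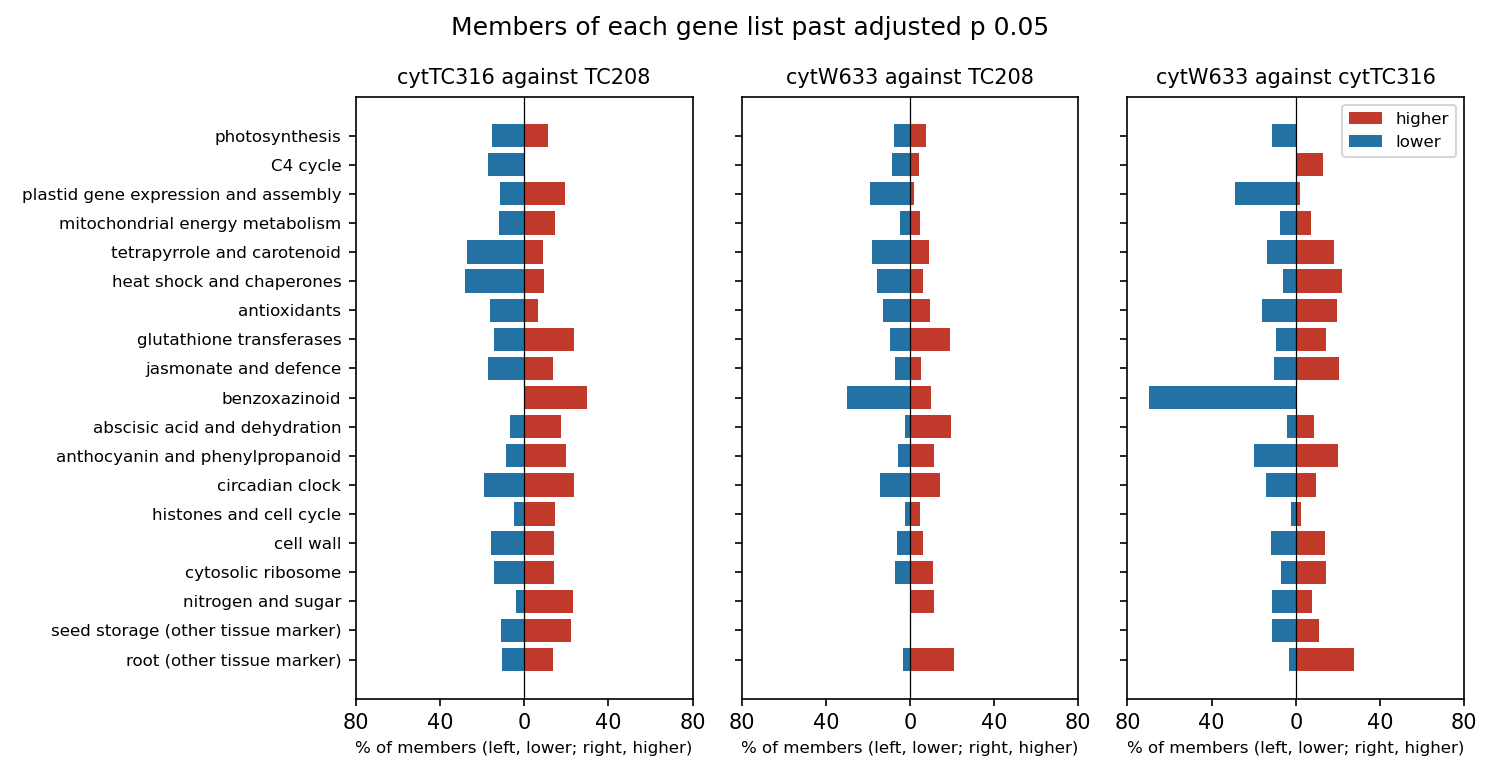
Percent of each list's tested members that were past the test (adjusted p under 0.05), lower to the left and higher to the right of 0, for the 19 lists by symbol in each of the 3 comparisons. Between the cytolines 7 of 10 benzoxazinoid genes were lower in cytW633. Whether members of a list neighbour each other in gene order was not tested.

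The other earlier lists, fixed before the data were examined, had few measured members. Of 18 jasmonate and oxylipin genes there were 1 higher and 3 lower in cytTC316, 1 and 1 in cytW633, and 1 and 0 in cytW633 against cytTC316. Of 8 cell wall genes there were 0 higher and 1 lower in cytTC316, 1 and 1 in cytW633, and 4 and 1 in cytW633 against cytTC316. The counts for 8 C4 cycle genes were 1 higher and 1 lower in cytTC316, 0 and 0 in cytW633, and 1 and 0 in cytW633 against cytTC316, and for 5 pentatricopeptide repeat proteins they were 1 higher and 0 lower in cytTC316, 0 and 0 in cytW633, and 0 and 1 in cytW633 against cytTC316. Adjusted over the list alone, these lists gave 1 and 3 (cytTC316), 1 and 1 (cytW633) and 1 and 0 (between cytolines) for jasmonate and oxylipin, 0 and 1 (cytTC316), 1 and 1 (cytW633) and 4 and 1 (between cytolines) for cell wall, 1 and 1 (cytTC316), 0 and 0 (cytW633) and 1 and 0 (between cytolines) for C4 cycle, 2 and 0 (cytTC316), 0 and 0 (cytW633) and 0 and 3 (between cytolines) for pentatricopeptide repeat proteins. None of these 4 lists passed the camera test, with a lowest adjusted p of 0.0606.

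Lists of fewer than 5 members gave counts only. Of 4 defence proteins, 3 were higher in cytW633 than in cytTC316, the chitinase genes chiI (GRMZM2G145461, 6.45-fold), chiB (GRMZM2G005633, 4.37-fold) and chitinase (GRMZM2G453805, 2.68-fold), and 1 was lower in cytTC316 than in TC208. Of 2 genes of alternative respiration, 1, Aox (GRMZM2G125669), was lower in cytW633 than in cytTC316. Adjusted over the list alone, 1 was higher and 1 lower there, with a list mean log2 fold change of 0.51. Of 3 dehydration genes, 1 was higher in cytW633 than in TC208 and 1 than in cytTC316. Among markers of hour and tissue, 1 of 2 clock genes, the GIGANTEA gene gigz1b (GRMZM5G844173), was higher in cytW633 than in TC208, 1 of 2 seed storage genes was lower in cytTC316 than in TC208 and 1 higher in cytW633 than in cytTC316, and 1 of 2 root genes was higher in cytW633 than in TC208 and 1 than in cytTC316. No member of the histone, invertase and further organelle gene expression lists (1, 1 and 4 genes) changed.

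Several of these calls depended on which arrays were used. Of 9 fits with 1 array left out, gigz1b lost its call against TC208 in 7, glb2 (GRMZM2G026703) in 4, chiI in 1 and dehydrin3 (GRMZM2G373522) in 1. Between the cytolines chitinase lost its call in 7, glb2 in 4, Aox in 4, ys1 (GRMZM2G156599) in 3 and chiB in 1. Chitinase reversed with the slide as a fixed block (log2 fold change -0.27). Of genes counted in the larger of the earlier lists, PPR10 (GRMZM2G177169) lost its call in 6 fits and PDK1 (GRMZM2G097821) in 7, both in cytTC316, and lac4 (GRMZM2G072780) in 6 in cytW633, where it was called on 1 of its 2 probes (log2 fold change 0.37, adjusted p 0.244 on its brighter probe). Between the cytolines crp1 (GRMZM2G083950, called on 1 of its 2 probes) lost its call in 8 and Laccase-7 (GRMZM2G094375, on 1 of its 3 probes) in 7.

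Some genes were well above background on every array of one line and on none of the others. There were 261 such genes for TC208, 472 for cytTC316 and 191 for cytW633. Other sets of 3 arrays give no reference for these counts, since probes were kept only if well above background on all arrays of a line. Well above background on all arrays except those of 1 line were 906 genes for TC208, his2b5 and TIFY4 among them, 363 for cytTC316, PER2 and EREB85 among them, and 96 for cytW633, HB115 among them, against at most 92 for another set. Sets with 1 array of each line could hold none by the same rule. Detection also differed by line. Of all probes, 42.4 to 43.1% were well above background on the TC208 arrays and 44.9 to 47.7% on those of the cytolines. Of the on or off genes, 2154 of 2289 were measured by 1 kept probe.

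Genes changed at least 2-fold were not spread evenly along the genome. Over the 14168 genes that could be placed in gene order, windows of 50 neighbours held 0 to 42% such genes for cytTC316 against TC208, 0 to 38% for cytW633 against TC208 and 0 to 40% between the cytolines. The SD over windows was 10.1, 8.61 and 8.20 percentage points, where the highest of 1000 shuffles of the gene order gave 5.24, 4.43 and 4.29.

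**Figure D5:**
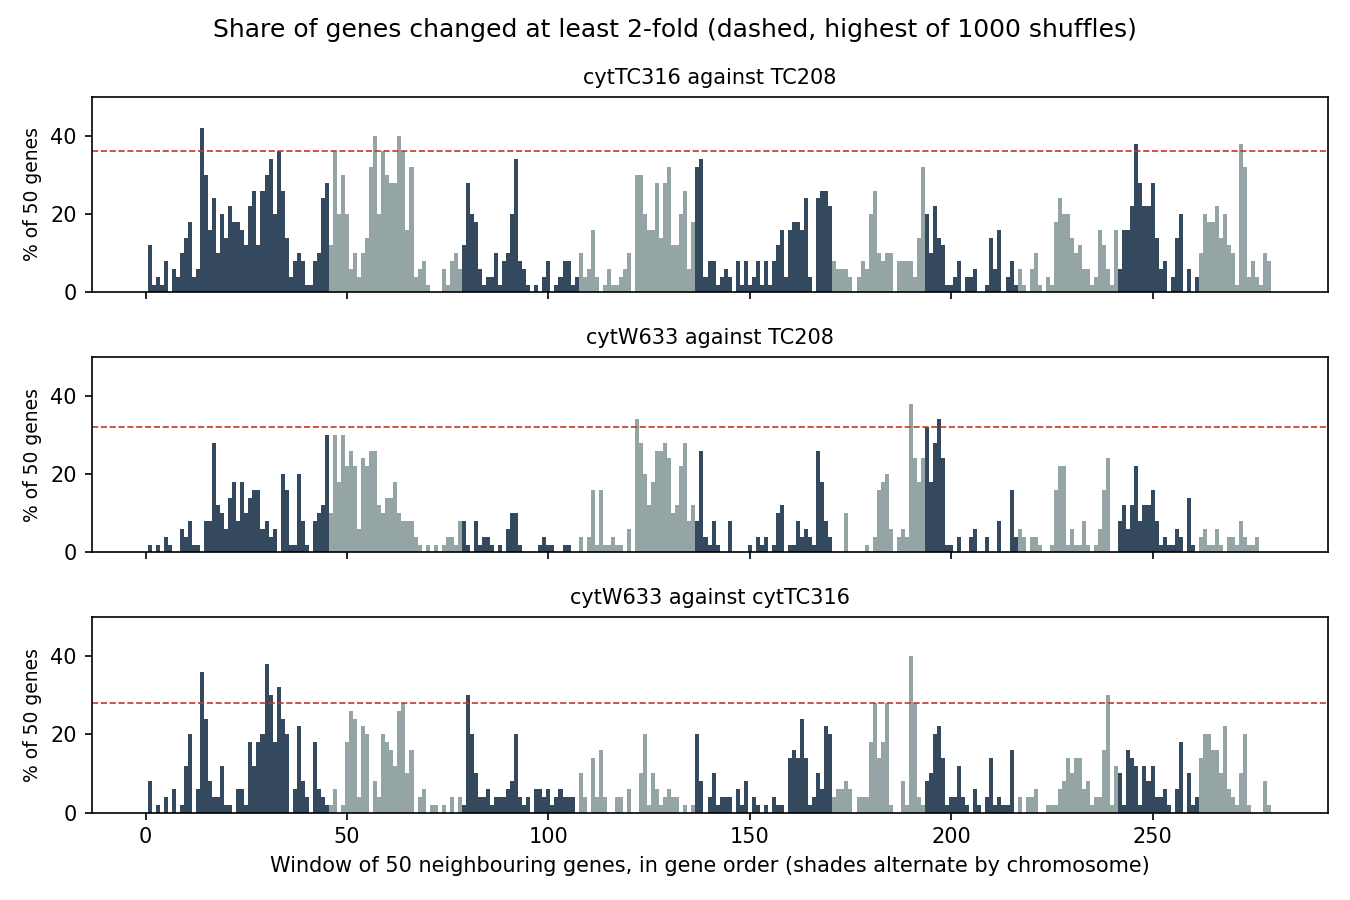
Percent of genes changed at least 2-fold (y axis) in each of the 279 windows of 50 neighbouring genes, in gene order (x axis; shades alternate by chromosome), for the 3 comparisons. Dashed lines mark the highest window in 1000 shuffles; runs of windows with many changed genes alternate with stretches near 0.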

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

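The cytolines differed in opposite directions from TC208 in 117 genes, each past the test in both cytolines. Of these, 56 were higher in cytTC316 and lower in cytW633, and 61 the reverse. All also passed the test of the difference between the cytolines. That follows almost by itself from 2 called changes of opposite sign, so it adds no support. The aquaporin gene PIP1-1 (GRMZM2G174807) changed by -2.80 ± 0.14 in cytTC316 and 1.37 ± 0.14 in cytW633 (log2 fold change against TC208 with SE), a difference of 4.17 with an adjusted p of 6.6e-08. A second aquaporin gene, TIP2-2 (GRMZM2G056908), went the other way, with 2.27 ± 0.19 in cytTC316 and -0.72 ± 0.19 in cytW633 (log2 fold change against TC208 with SE), a difference of -2.99 (adjusted p 5.5e-06). MAX1b (GRMZM2G023952), a cytochrome P450 of strigolactone synthesis, changed by -2.15 ± 0.20 in cytTC316 and 0.83 ± 0.20 in cytW633 (log2 fold change against TC208 with SE), a difference of 2.97 (adjusted p 7.4e-06). ciszog1 (GRMZM2G168474), which glucosylates the cytokinin cis-zeatin, changed by 1.47 ± 0.17 in cytTC316 and -0.73 ± 0.17 in cytW633 (log2 fold change against TC208 with SE), a difference of -2.20 (adjusted p 1.9e-05). MAX1b and ciszog1 were chosen after their values were seen. These are the named genes among the opposite ones whose lines do not overlap in any comparison, and the cause was not tested.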

How the results depend on the processing

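The tests of probes whose name carries Sp, of the percentile over all probes and of the slide in the list test were chosen after seeing the data; all other settings were fixed before. Counts of changed genes are given in the order cytTC316 against TC208, cytW633 against TC208, cytW633 against cytTC316 and both cytolines. With the slide as a fixed block they were 4225, 3500, 1179 and 1852, where 1 residual degree of freedom remained of 6. In that fit cytTC316 was represented by its array on slide 3 alone, also between the cytolines. The counts were 6368, 3897, 3790 and 2667 at 2-fold or more and 7622, 4400, 4002 and 2958 at an adjusted p under 0.01, and 4505, 2800, 2902 and 1781 on Sp probes, where 16347 genes were tested. With probes well above background on all 9 arrays, 4714 genes changed in cytW633 and 3024 in both. Leaving out 1 array gave 9389 to 12214, 5500 to 6979, 5242 to 7284 and 3847 to 4749; every other setting stayed within 1.5 times of the reported counts. With the slide as a fixed block the split between the cytolines was 696 higher and 483 lower (59.03% higher, where the reported split was 46.1%), and without a filter on dim probes the median of all genes shifted by -0.22 and -0.19 against TC208. The replicate numbers did not pair the arrays, since same-numbered arrays deviated together at correlations of -0.212 to 0.110 and 0 of 9 correlated best with their own number; a replicate block called 11085, 6278 and 6076 genes, 10716, 6052 and 5878 of them shared.

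The 5 list and comparison pairs past the camera test became 0 with an estimated correlation, 20 with fry, which does not compare a list with other genes, 9 with probes bright on all arrays, and 4 to 12 when 1 array was left out. With an estimated correlation the adjusted p of the called lists were 0.855 (plastid list, cytW633 against TC208), 0.597 (plastid list, between cytolines), 0.590 (benzoxazinoid), 0.597 (abscisic acid) and 0.400 (anthocyanin). With the slide as a fixed block the plastid list had 0.468 and 0.734 and the abscisic acid list 0.629, and after quantile normalisation the plastid list had 0.120 in cytW633 against TC208. Leaving out 1 array gave 0.00229 to 0.213 for the plastid list in cytW633 against TC208 and 0.0180 to 0.0984 for the abscisic acid list. Each called list kept its direction in every setting run on it. No alternative was run for organelle transcripts, since no gene model matched one.

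Of 246 calls of the chosen genes (12 of them of genes without a name), 163 were of genes measured in all 23 settings, and 57 of these held in all. The other 83 had no probe well above background on all arrays, and 63 of them held in every other setting. In the settings run on each, 230 of the 246 kept their direction; over settings, 490 of their 5575 values lost the call, 19 of these with the direction turned, and 24 values of other chosen genes gained one. Log2 fold changes that reversed were gln2 0.36, PDK1 -0.0871 (cytTC316 against TC208), PDK1 -0.0868 (cytW633 against TC208), gln2 -0.30 (cytW633 against cytTC316) without a filter on dim probes; fdx3 0.0751, Emb12 -0.0162, MSRA5.1 0.69, MTERF4 -0.44 (cytTC316 against TC208), pcna2 0.0255, rps13 -0.15 (cytW633 against TC208), MSRA5.1 -0.67, rps13 -0.35 (cytW633 against cytTC316) with probes bright on all arrays; fdx3 0.0751, Emb12 -0.0162, HO-1 0.22, MSRA5.1 0.69, MTERF4 -0.42 (cytTC316 against TC208), SMK2 -0.15, pcna2 0.22, rps13 -0.15 (cytW633 against TC208), MSRA5.1 -0.67, pcna2 0.0942, rps13 -0.35 (cytW633 against cytTC316) with the brightest probe of a gene, settings that drop or add probes that disagree; dhn1 -0.11, GI -0.0886 (cytTC316 against TC208), ZCN7 0.11, L29 0.12, chitinase -0.27 (cytW633 against cytTC316) with the slide as a fixed block; csh9 0.0187 (cytW633 against cytTC316) with array weights; and, when 1 array was left out, csh9 (cytW633 against cytTC316), which ranged from -0.226 (without cytW633 replicate 2) to 0.0371 and reversed without cytTC316 replicate 1, and IVR1 (GRMZM2G394450), cytW633 against TC208, which ranged from -0.205 (without cytW633 replicate 3) to 0.0190 and reversed without cytW633 replicate 2. The cause of the other changes was not tested. Signals near background limit the dim genes. A fold was written as at least a value where no array of a line was well above background. It was as measured where some were.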

Other observations

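The tests of nuclear segments and gene copies behind the runs, of genes with 1 probe or without a following probe, of runs among the on or off genes, and of shared controls, slide position and TC208 segments behind the shared changes were chosen only after the result was seen. Genes changed at least 2-fold lay in runs of neighbouring genes, and being changed correlated between genes 10 places apart at 0.0630 or more in all 3 comparisons, where shuffles reached at most 0.0284. Copies of one gene that lie side by side could share sequence under a probe, but the correlation reached as high as 0.0794 at 10 places. Differences between arrays of 1 slide showed the same correlation, 0.0620 or more within slides 1, 2 and 3 against at most 0.0290 in shuffles, which argues against the slide as its cause. A candidate explanation is nuclear segments that differ between the lines, such as remnants of the cytoplasm donor's nucleus, and this stays a hypothesis, since no genotype was used here and an effect of the cytoplasm on groups of neighbouring genes was not tested.

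Genes that were on in some lines and off in others, such as his2b5 and TIFY4, could reflect a sequence difference under a probe rather than a change in transcript. Among 350 genes with several probes, of which 1 probe drawn at random was on or off, 58.4% of the 598 other probes differed at least 2-fold the same way. Only 135 of the 2289 on or off genes had several probes, so most of the 350 were not on or off as genes. Where other probes follow, this argues against a sequence difference under that 1 probe alone. It cannot tell a difference under all probes of a gene from a change in transcript. A difference under 1 probe stays open for the 128 of these 350 where no other probe followed. It also stays open for 2154 of the 2289 on or off genes, his2b5 and TIFY4 among them, since they had 1 kept probe. For the 385 on or off genes that could be placed, the correlation at 10 places, 0.0150, lay within the shuffles (at most 0.0313), so runs were not shown for them. Within slides 1, 2 and 3 at least 74.1% of the on or off genes differed 2-fold the same way. The arrays of these slides also served to define the genes, so agreement was partly built in. A part by the slide stays open.

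For the 4855 genes changed in the same direction in both cytolines, shared controls would give a covariance of the fold changes like that simulated, at most 0.0294, but it was 0.635 over all genes, which argues against the shared arrays as the whole cause. All TC208 arrays lay at 1 slide position, but genes changed at least 2-fold in both correlated 10 places apart at 0.0545 (at most 0.0234 in shuffles), while the spot order did not follow gene order (-0.00430 at 10 places, at most 0.0304 in shuffles); this argues against position as the whole cause. Their share varied over windows with an SD of 6.46 percentage points, above the 3.42 reached by shuffles, and segments of the TC208 nucleus that both cytolines lack may account for part of them. A response to leaving the TC208 cytoplasm stays open and cannot be separated here, since both cytolines differ from TC208 in cytoplasm and in array position.

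Other splits of the arrays were run as well. The 10 splits of 6 arrays are too few for a share under 0.05: 12179, 7184 and 7246 genes were called for the real lines, 1 split of 10 each, and at most 0, 1 and 0 for other splits. For genes changed in both cytolines, 1 of 100 groupings of the 9 arrays, the real one, gave as many as the real 4855. The highest other grouping gave 2905 and the median of the others was 0. This shows that the arrays group by line. It cannot test how much sharing the common controls or the slide position add, since the other groupings mix the lines. For list shifts, 79 of 100 groupings gave at least the real 5 pairs (median of the others 12, highest 33), so chance cannot be excluded for the number of shifted lists, and groupings with several times the real number point to a structure of the samples; they mix arrays of different lines, and the source of their shifts was not tested.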
